A study of Rattus norvegicus with 18 samples.

How the data were processed

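Cardiomyocytes from day 1 ventricles (n = 24) were purified on Percoll gradients, plated at 250000 cells per 100 mm dish and held for 24 h in cardiac medium. Of 18 samples, 6 were extracted at time zero. The other 12 were diluted to 50% with unconditioned or stem cell conditioned hESC medium, with FBS at 5% and HS at 10%, and extracted at 24 h or 48 h. Per the labels, biotin-labelled RNA was hybridised to 1-colour CodeLink arrays of 2 designs, with 12 arrays on the larger and 6 on the smaller one. The deposited values are linear intensity, and scanner, software, background correction and normalization are not stated. The values looked background-subtracted, with 0.0001 as the lowest, and medians that differed between arrays spoke against a normalization between arrays. They ran from 70.3 to 143.6 in the larger table and from 213.8 to 415.7 in the smaller one.

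The larger table held values for 33849 probes, of which 16753 were assigned to 1 gene, 165 to several and 16931 to none. The smaller table held 9906 probes (7290, 87 and 2529). No pair of arrays held identical values. Groups were time zero (replicates 3 to 6 on the larger design, 1 and 2 on the smaller), and unconditioned and conditioned medium at 24 h and 48 h (replicates 2 and 3 on the larger design, 1 on the smaller). Replicate numbers follow the order of the deposited samples and carry no pairing.

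Each array was scaled to the median of its table, values were floored at 0.05 of that median (intensity 4.78 in the larger table) and taken to log2, and probes with a mean at or below the 30th percentile were left out, which kept 23694 probes for 9953 genes. All groups of the larger table were fitted together with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with an intensity trend), with 7 residual and 10.4 prior degrees of freedom. Calls needed a Benjamini-Hochberg adjusted p under 0.05 over all probes. Genes were represented by the probe with the highest mean, only where assigned to 1 gene. No coordinates were used, since no genome build was given, and probe sequences were not analysed here. The smaller table was scaled and filtered in the same way (6934 probes) and compared by direction over 4613 shared genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

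The comparisons, alternatives, gene lists and the rule for naming genes were fixed before the data were examined. For conditioned against unconditioned medium over both times, and for 24 h and 48 h against time zero, the rule named the 10 highest and 10 lowest changes among called genes whose arrays did not overlap, and for the other comparisons 5 and 5. Where fewer passed, the smallest p in that direction filled the number. Up to 4 members with the smallest p were named for a list, and Myh6, Nppa, Tnnt2, Col1a1, Ccnb1, Mki67, Cdk1 and Ccnd1 were named in advance. In all 26 lists with 687 genes were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison. An estimated correlation was the first alternative.

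Other alternatives were quantile and cyclic loess normalization, no filter or one at the 50th percentile, a floor of 0.2 or a pseudocount of 0.5 of the median, no intensity trend, array weights, only the groups compared, probes of a gene averaged, both tables with the design as block, the smaller table alone, fry in place of camera, and each array left out in turn. Scaling to the 75th percentile, leaving out the 3 arrays that stood apart, and an estimated correlation joined with another setting were chosen after the data were seen. The pipeline was tested on simulated data in which 200 of 23694 probes were changed. For conditioned against unconditioned medium over both times, 8.5% of 2-fold, 72.5% of 4-fold and 91.0% of 8-fold changes were called, and for the difference between the medium effects 0%, 6.0% and 72.0%. Of 200 unshifted gene sets 6 had a camera p under 0.05. The simulated noise was independent between probes and the sets were random, so this does not test the preset correlation for genes that vary together.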

Results

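Gene expression was measured in 18 samples of neonatal rat cardiomyocytes, the contractile cells of the heart muscle. At time zero 6 samples were extracted, and the other 12 were diluted to 50% with unconditioned or stem cell conditioned hESC medium for 24 h or 48 h. The title of the series names the question, whether secreted factors of stem cells make these cells proliferate. Tests used the 12 arrays of the larger array design, 4 of time zero and 2 of each other group. The 6 arrays of the smaller design served to compare directions. The labels do not identify dishes, so whether the designs shared RNA of the same dishes is not known. The labels name no separate preparations of cells, so p-values measure only the spread between arrays, which may be technical.

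Log2 changes are given ± SE relative to the median change of all probes in the same comparison, and intensities as mean ± SD of median-scaled values. That median was 0.09 for conditioned against unconditioned medium over both times, 0.01 at 24 h and 0.18 at 48 h. It was 0.18 for 24 h against time zero, 0.08 for 48 h against time zero, -0.09 for 48 h against 24 h and 0.18 for the difference between the medium effects. Adjusted p-values and calls of single genes and probes test the change before this median was subtracted. Where the median is positive, an increase therefore passes more easily than a decrease of the same shown size.

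Arrays did not separate by group alone. The first principal component held 35.1% of the variance and set time zero replicates 4 and 5 and unconditioned 48 h replicate 2 apart from the other 9 arrays. Those 3 arrays had a ratio of the upper to the lower quartile of intensity of 22.5, 22.4 and 25.7, against 38.7 to 47.8 on the others. Pearson's r over probes was 0.97 between the conditioned replicates at 24 h and at 48 h. It was 0.95 between the unconditioned replicates at 24 h and 0.90 at 48 h. Between time zero replicates it ran from 0.84 (4 and 6) to 0.95 (3 and 6).

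**Figure D1:**
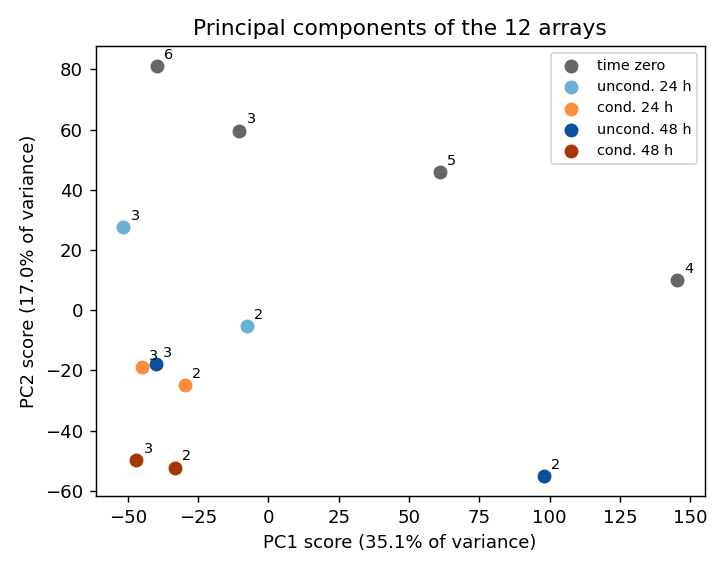
Scores of the 12 arrays of the larger design on the first and second principal components of log2 intensity, which held 35.1% and 17.0% of the variance. Each point is 1 array, coloured by group and numbered by replicate, and time zero replicates 4 and 5 and unconditioned 48 h replicate 2 lie to the right of the rest.

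The central comparison set conditioned against unconditioned medium over both times (4 arrays against 4). Reg3b (probe 279110), a secreted C-type lectin, rose by 5.49 ± 0.33 (adjusted p = 8.9e-08), from 113 ± 21.8 to 2611 ± 375 at 24 h and from 50.5 ± 27.5 to 4546 ± 243 at 48 h. Osmr, the receptor subunit for oncostatin M, rose by 4.59 ± 0.79 (adjusted p = 0.0050), a size that depends on the floor, where 3 of the 4 unconditioned arrays lay (2.65 with a floor of 0.2 of the median). Myh3 (probe 294057), the embryonic myosin heavy chain, fell by 5.12 ± 0.32 (adjusted p = 1.2e-07), from 3707 ± 954 to 101 ± 9.13 at 48 h. Myh2, a fast skeletal myosin heavy chain, fell by 3.93 ± 0.32 (adjusted p = 4.1e-06). Probe sequences were not analysed here, so cross-hybridisation among myosin paralogs stays open.

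Other genes with large increases were Kcnj8, the pore subunit Kir6.1 of an ATP-sensitive potassium channel (5.01 ± 0.77), the phosphatase Ppef1 (4.10 ± 0.60), the phosphatase 2A regulatory subunit Ppp2r2b (3.16 ± 0.38) and Cyb561, a membrane cytochrome of secretory granules (2.74 ± 0.31). Was (2.55 ± 0.58), the anticoagulant receptor thrombomodulin, Thbd (2.53 ± 0.24), the RNA helicase Mtrex (2.31 ± 0.44) and galectin-3, Lgals3 (2.18 ± 0.24), also rose. The largest adjusted p among these 8 genes was 0.034, for Was, whose call ended with a floor of 0.2 of the median (1.76, adjusted p = 0.063). Cd74, the MHC class II invariant chain, fell, with a change of -3.79 ± 0.54 that depends on the floor, where 3 of the 4 conditioned arrays lay. Genes that fell also included Dhrs7c (-3.62 ± 0.40), Tril (-3.50 ± 0.41), the proton-potassium ATPase Atp12a (-3.18 ± 0.29) and the fast skeletal myosin light chain Myl11 (-3.10 ± 0.59). The calcium pump Atp2b2 (-2.73 ± 0.43), the amino acid transporter Slc7a3 (-2.69 ± 0.47) and elastin, Eln (-2.68 ± 0.30), fell as well. The largest adjusted p of these 8 genes was 0.016, for Myl11. These changes compare the media, and levels at time zero differed from gene to gene, as for 3 genes chosen here after their values were seen. Tril rose from time zero in unconditioned medium at 24 h (2.85 ± 0.50, adjusted p = 0.0049) and was at -1.37 ± 0.50 (adjusted p = 0.26) in conditioned medium, and Atp12a likewise rose by 2.81 ± 0.35 (adjusted p = 4.2e-04) and was at -0.79 ± 0.35 (adjusted p = 0.44). Mtrex fell from time zero in unconditioned medium at 24 h (-3.16 ± 0.54, adjusted p = 0.0099) and was at 0.51 ± 0.54 (adjusted p = 0.61) in conditioned medium. The call of Cd74 ended with a floor of 0.2 of the median (-1.88, adjusted p = 0.072) or a pseudocount (-1.28, 0.12). A floor of 0.2 of the median also gave smaller changes for Kcnj8 (4.46), Ppef1 (3.40), Mtrex (1.91), Dhrs7c (-2.99), Myl11 (-2.24), Atp2b2 (-2.21) and Slc7a3 (-2.17). With no filter on level the calls of Kcnj8, Was, Mtrex, Atp2b2 and Slc7a3 ended (adjusted p from 0.072 to 0.13).

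**Figure D2:**
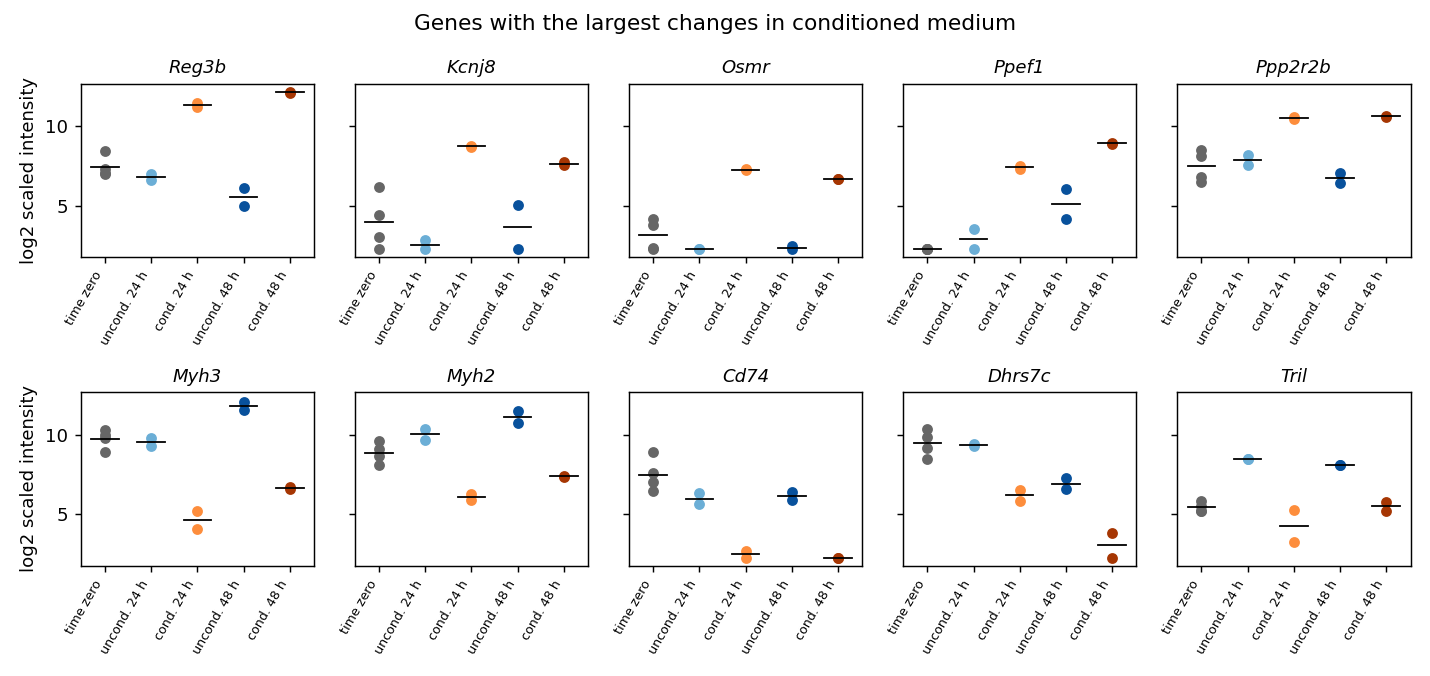
Log2 of median-scaled intensity on each array of the larger design for the 5 genes with the highest and the 5 with the lowest changes among those named for conditioned medium. Points are arrays (4 at time zero, 2 in each other group) and bars are group means. Reg3b was above 11 on the log2 axis only in conditioned medium, and Myh3 was below 7 only in conditioned medium.

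Of 23694 probes tested with limma, 218 changed, 149 higher and 69 lower in conditioned medium. With quantile normalization 920 changed, 500 higher and 420 lower, and 215 of the 218 were among them. Leaving out the 3 arrays that stood apart, a setting chosen after the data were seen, leaves 1 array of unconditioned 48 h. The other arrays of the comparison stay the same, so the calls of that fit are no separate check of the 218. By camera 4 of 26 gene lists passed, and 9 with quantile normalization, but 0 with an estimated correlation and 1 with an estimated correlation and quantile normalization. Of 49 called genes that the smaller design also measured, 47 had the same sign there. Reg3b and Osmr were not measured there, while Myh3 was at -4.46, Cyb561 at 2.23 and Lgals3 at 2.34. Thbd was at 0.87.

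Over both times muscle genes lay lower in conditioned medium, with a larger gap at 24 h than at 48 h under median scaling. For the sarcomere this difference between the times did not pass with quantile normalization. Unconditioned 48 h replicate 2, an array that stood apart, narrowed the sarcomere gap at 48 h. Relative to time zero the sarcomere list mean was 0.22 in unconditioned and -0.33 in conditioned medium at 24 h. At 48 h it was -0.07 and -0.22, and single arrays of the media overlapped. Smooth muscle and pericyte means were 0.56 and -0.02 at 24 h, and 0.75 and 0.71 at 48 h. Of 27 measured sarcomere genes, 24 were below the median of all probes, with a list median of -0.33 (camera adjusted p = 2.0e-06, but adjusted p = 0.95 with an estimated correlation). Myom2, an M-band protein, fell by 1.80 ± 0.29 (adjusted p = 0.0050), and no other sarcomere gene passed over all probes. Adjusted over the list alone, 1 rose and 1 fell. Nebl stood at 1.13 ± 0.30 (adjusted p = 0.069), the atrial myosin light chain Myl7 at -0.82 ± 0.25 (adjusted p = 0.24) and Ldb3 at -0.83 ± 0.27 (adjusted p = 0.26). Among 24 genes of calcium handling and ion channels (median -0.30, camera adjusted p = 0.025, adjusted p = 0.95 with an estimated correlation), Hrc, a calcium-binding protein of the sarcoplasmic reticulum, fell by 1.73 ± 0.29. The gap junction gene Gja5 rose by 1.59 ± 0.29 and triadin, Trdn, by 1.46 ± 0.28, and the other 21 did not pass. The counts adjusted over the list alone were also 2 and 1. The 12 smooth muscle and pericyte genes had a median of -0.22 (camera adjusted p = 0.011, adjusted p = 0.95 with an estimated correlation). None of them passed over all probes, and 2 fell when adjusted over the list alone, Myh11 at -1.07 ± 0.25 and Cnn1 at -0.95 ± 0.24.

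Mitosis genes lay lower in conditioned than in unconditioned medium. The 42 measured genes of G2/M and mitosis had a median of -0.32, with 35 below the median of all probes (camera adjusted p = 1.2e-06, adjusted p = 0.95 with an estimated correlation). None passed on its own, over all probes or adjusted over the list alone. Pbk stood at -0.92 ± 0.29 (adjusted p = 0.24), Nusap1 at -0.81 ± 0.28 (adjusted p = 0.31) and Ccnb1, the cyclin of mitotic entry, at -0.64 ± 0.28 (adjusted p = 0.51). Mki67, a proliferation marker, was at -0.27 ± 0.27 (adjusted p = 0.87), Cdk1 at -0.28 ± 0.34 (adjusted p = 0.90) and Ccnd1 at 0.43 ± 0.29 (adjusted p = 0.56). On the smaller design Cdk1 was at 0.86 and 12 of 18 mitosis genes were below the median of all genes. The 33 genes of DNA replication and G1/S had a median of -0.11 (camera adjusted p = 0.20) and the 12 cell cycle inhibitors one of -0.13 (camera adjusted p = 0.55).

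Beside smooth muscle and pericyte genes, no marker list of another cell type passed in this comparison, while the leukocyte gene Cd74 fell and the matrix gene Fn1, fibronectin, rose (1.61 ± 0.26, adjusted p = 0.0024). The median was -0.23 for 25 fibroblast and matrix genes (camera adjusted p = 0.087), -0.29 for 13 leukocyte genes (camera adjusted p = 0.057), -0.08 for 4 erythroid genes (camera adjusted p = 0.59) and -0.00 for 18 endothelial genes (camera adjusted p = 0.68, with a test direction upward). Single genes of signalling and metabolic lists also rose, while the lists did not pass. These were the glycolytic enzyme Aldoc (1.58 ± 0.28), the lipase inhibitor Angptl4 (1.68 ± 0.33), the hypoxia target Ndrg1 (1.90 ± 0.30), the transcriptional repressor Tgif1 (1.31 ± 0.28), the transcription factor Cebpd (1.54 ± 0.27) and the adhesion molecule Icam1 (1.27 ± 0.29). Their list medians were 0.07 for glycolysis (camera adjusted p = 0.55), -0.04 for fatty acid oxidation and PPAR targets (0.89, with a test direction upward), 0.02 for hypoxia targets (0.59), 0.15 for TGF-beta and BMP targets (0.55) and -0.07 for inflammatory response (0.79).

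Interferon response genes had the highest list median, 0.40, with 17 of 20 above the median of all probes (camera adjusted p = 0.057), and none passed on its own. The immediate early and ERK response list stood at 0.19 (camera adjusted p = 0.49), p53 targets at 0.07 (0.82), NRF2 targets at 0.01 (0.82, with a test direction downward) and cholesterol synthesis and SREBP targets at -0.02 (0.55). Wnt targets stood at -0.05 (0.82), the respiratory chain at -0.11 (0.071), the amino acid and ER stress response at -0.15 (0.19) and Notch targets at -0.19 (0.19). Cardiac stress markers stood at -0.19 (0.19) and cardiac transcription factors at -0.24 (0.057). With quantile normalization the lists of DNA replication, cardiac transcription factors, the respiratory chain, the amino acid and ER stress response and the interferon response passed as well (camera adjusted p from 0.0047 to 0.044), but none of them with an estimated correlation. Nppa, which encodes atrial natriuretic peptide, was at -0.19 ± 0.26 (adjusted p = 0.94) and the troponin Tnnt2 at 0.08 ± 0.28 (adjusted p = 0.89). Myh6 was not above the filter on level and was not tested.

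At 24 h (2 arrays against 2), conditioned medium raised Reg3b by 4.53 ± 0.47 (adjusted p = 1.8e-04), Mtrex by 3.65 ± 0.62 (adjusted p = 0.014) and Thbd by 2.70 ± 0.35 (adjusted p = 0.0011). Kcnj8 (6.19 ± 1.09, adjusted p = 0.017) and Ppef1 (4.52 ± 0.85, adjusted p = 0.026) rose as well, by sizes that depend on the floor, where 1 of the 2 unconditioned arrays lay for each gene (5.19 and 3.16 with a floor of 0.2 of the median). Myh3 fell by 4.92 ± 0.45 (adjusted p = 4.6e-05), and Tril (-4.23 ± 0.58), Myh2 (-3.95 ± 0.45), Atp2b2 (-3.83 ± 0.61) and Atp12a (-3.61 ± 0.41) fell as well. In all, 58 probes changed, 30 higher and 28 lower, and 302 with quantile normalization. Most calls were lower without conditioned 24 h replicate 2 (4 higher, 15 lower) or 3 (4 higher, 22 lower). All 14 called genes measured on the smaller design had the same sign there. The call of Thbd ended with both tables fitted together (2.17, adjusted p = 0.18), and with no filter on level those of Kcnj8, Ppef1, Mtrex, Tril and Atp2b2 ended (adjusted p from 0.078 to 0.22). With a floor of 0.2 of the median Mtrex stood at 2.82 and Atp2b2 at -2.82, and with a pseudocount the call of Mtrex ended (1.64, adjusted p = 0.086).

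Muscle genes lay lower at 24 h as well. Of 27 sarcomere genes 26 were below the median of all probes, with a list median of -0.60 (camera adjusted p = 3.0e-09, adjusted p = 0.94 with an estimated correlation), and only Myom2 passed, having fallen by 2.26 ± 0.41 (adjusted p = 0.021). Smooth muscle and pericyte genes had a median of -0.51 (camera adjusted p = 3.0e-05, adjusted p = 0.94 with an estimated correlation), with Cnn1 at -1.68 ± 0.35 (adjusted p = 0.057), and 2 of 12 fell when adjusted over the list alone. Cardiac stress markers had a median of -0.44 (camera adjusted p = 0.0048), calcium handling genes one of -0.42 (0.0070), the respiratory chain one of -0.38 (3.3e-05) and G2/M and mitosis one of -0.32 (1.5e-04). With an estimated correlation each of these 4 lists had an adjusted p = 0.94. With quantile normalization the medians were -0.35 for the sarcomere (adjusted p = 0.0057 with an estimated correlation) and -0.21 for the respiratory chain, and the stress markers no longer passed (-0.16, camera adjusted p = 0.12), nor did the mitosis genes with both tables fitted together (-0.32, 0.16).

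At 48 h (2 arrays against 2), Reg3b rose by 6.43 ± 0.47 (adjusted p = 1.6e-06), Ppp2r2b by 3.70 ± 0.53 (0.0035), Camk2n1, an inhibitor of the calmodulin-dependent kinase CaMKII, by 2.93 ± 0.50 (0.013), Cyb561 by 2.79 ± 0.43 (0.0045) and Lgals3 by 2.44 ± 0.34 (0.0029). Genes that fell were Myh3 (-5.35 ± 0.45, 2.0e-05), Dhrs7c (-4.08 ± 0.56, 0.0044), Myh2 (-3.92 ± 0.45, 0.0013), Slc7a3 (-3.76 ± 0.66, 0.041) and Eln (-3.25 ± 0.42, 0.0035). The call of Slc7a3 ended without the 3 arrays that stood apart, and with no filter on level the calls of Ppp2r2b, Camk2n1, Cyb561, Dhrs7c, Myh2, Slc7a3 and Eln ended (adjusted p from 0.057 to 0.25). Dhrs7c and Slc7a3, each with 1 of 2 conditioned arrays at the floor, stood at -2.85 and -2.74 with a floor of 0.2 of the median, and the call of Dhrs7c ended with a pseudocount (-1.79, adjusted p = 0.25). In all, 35 probes changed, 26 higher and 9 lower, and 170 with quantile normalization. The excess of higher calls was lost without conditioned 48 h replicate 3 (2 higher, 9 lower) or 2 (13 higher, 18 lower). All 12 called genes measured on the smaller design had the same sign there. Aldoc, of the glycolysis list, rose by 1.94 ± 0.40 (adjusted p = 0.041).

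The 42 mitosis genes had a median of -0.37 at 48 h, with 38 below the median of all probes (camera adjusted p = 1.2e-05, adjusted p = 1.00 with an estimated correlation), and none passed on its own. The 13 leukocyte genes had a median of -0.43 (camera adjusted p = 0.029, adjusted p = 0.37 with an estimated correlation), and Cd74 was at -4.08 ± 0.76 (adjusted p = 0.051), with both conditioned arrays at the floor. That list no longer passed with quantile normalization (-0.35, camera adjusted p = 0.31) or without the 3 arrays that stood apart (-0.15, 0.70). Sarcomere genes had a median of -0.24 (camera adjusted p = 0.072, adjusted p = 1.00 with an estimated correlation) and passed with quantile normalization (-0.32, camera adjusted p = 2.6e-05).

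The test of whether the medium effect differed between 24 h and 48 h called no gene with limma, with 518 probes at an unadjusted p under 0.05, while the smaller table alone gave 110 calls and the fit without the 3 arrays that stood apart gave 17. Both of these fits rest on lone arrays, which were assumed to vary like the other groups, since the smaller table has 1 array in each medium group and unconditioned 48 h keeps 1 without the 3 arrays. The smallest p among increases belonged to Fn3k (2.22 ± 0.63), Edf1, Klf15, Selenbp1 and Nacad, and among decreases to Tmigd1 (-3.44 ± 0.82), Calb2, Fmo2, Yap1 and Or1f32, all with an adjusted p = 1.00. Across genes the effects at the separate times had a Spearman correlation of 0.41, which shares no array, although genes are not independent replicates. All 31 genes called at 24 h had the same sign at 48 h, all 16 called at 48 h had the same sign at 24 h, and 11 were called at both times.

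By list, the effect at 48 h lay above that at 24 h for the respiratory chain (0.45, camera adjusted p = 9.8e-05), fatty acid oxidation and PPAR targets (0.43, 0.0023), smooth muscle and pericyte genes (0.41, 0.0035), glycolysis (0.37, 0.040), the sarcomere (0.31, 0.0042) and cardiac stress markers (0.23, 0.010). With an estimated correlation each had an adjusted p = 0.92. With quantile normalization only fatty acid oxidation (0.35, camera adjusted p = 0.0035) and smooth muscle genes (0.17, 0.049) passed. Unconditioned 48 h replicate 2, an array that stood apart, lay below replicate 3 in each of these lists and so adds to the differences. Its list mean relative to time zero was -0.36 against 0.12 for glycolysis and -0.42 against 0.001 for fatty acid oxidation.

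The comparison of 24 h with time zero set the 4 arrays of both media against 4 arrays, and it joins dilution, added time in culture and handling. Cdkn2b, the cell cycle inhibitor p15, rose by 5.13 ± 0.54 (adjusted p = 2.1e-05), Il17re by 3.74 ± 0.43, Fgl2 by 3.50 ± 0.31, galectin-9, Lgals9, by 3.30 ± 0.31 and Thbd by 3.19 ± 0.24. Mustn1 rose by 3.16 ± 0.37, Entpd1, an ectonucleotidase, by 3.10 ± 0.48, Eva1a by 3.09 ± 0.45, Nab2, a corepressor of Egr factors, by 3.03 ± 0.60 and Abi3 by 2.95 ± 0.44. Igfbp5, a binding protein of insulin-like growth factors, fell by 4.63 ± 0.71. Cd74 (-3.45 ± 0.54) and the inhibitors of basic helix-loop-helix factors Id2 (-3.11 ± 0.44) and Id1 (-2.48 ± 0.28) fell. So did Perm1, a muscle regulator of oxidative genes (-2.93 ± 0.30), Plcl1 (-2.74 ± 0.68), Lrrn4cl (-2.49 ± 0.59), Ddx25 (-2.48 ± 0.51), Dusp26 (-2.29 ± 0.38) and Ntrk2, the receptor TrkB (-2.19 ± 0.31). The largest adjusted p of these 20 genes was 0.048, for Plcl1. For Mustn1, Abi3, Plcl1 and Ddx25 a single time zero array lay far from the other 3. The calls of Plcl1, Ddx25 and Lrrn4cl ended without the 3 arrays that stood apart, and these and that of Igfbp5 ended with no filter on level (adjusted p from 0.056 to 0.21). Arrays at the floor made some sizes depend on it, and with a floor of 0.2 of the median the changes were 3.95 for Cdkn2b, 2.57 for Il17re, 2.32 for Eva1a, 1.60 for Nab2, -2.55 for Cd74 and -1.85 for Lrrn4cl.

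Of 23694 probes 743 changed, 670 higher and 73 lower. With quantile normalization 1821 changed, 1233 higher and 588 lower, and without the 3 arrays 1713 changed, 915 higher and 798 lower. On the smaller design 219 of 220 called genes had the same sign, with Thbd at 0.54 there.

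Of 25 immediate early and ERK response genes 10 rose and none fell (16 adjusted over the list alone), with a median of 0.86 (camera adjusted p = 8.3e-08, adjusted p = 0.90 with an estimated correlation). Examples were Egr1 (1.81 ± 0.30), Phlda1 (1.62 ± 0.28), Etv4 (1.84 ± 0.32) and the phosphatase Dusp5 (1.70 ± 0.31). Of 18 endothelial genes 5 rose and 1 fell (10 and 1 adjusted over the list alone), with a median of 0.70 (camera adjusted p = 0.0015, adjusted p = 0.90 with an estimated correlation), led by the receptor Tek (1.91 ± 0.28). Of 25 fibroblast and matrix genes 6 rose and none fell (9 adjusted over the list alone), with a median of 0.52 (camera adjusted p = 1.5e-04, adjusted p = 0.90 with an estimated correlation), among them Lox, which cross-links collagen (1.56 ± 0.26), and Fbln2 (1.56 ± 0.27). Of 42 mitosis genes 3 rose, Cks2 (1.00 ± 0.28), Mad2l1 (0.83 ± 0.26) and Foxm1 (0.75 ± 0.24), and 23 when adjusted over the list alone (median 0.52, camera adjusted p = 1.5e-04, adjusted p = 0.90 with an estimated correlation). The DNA replication list had a median of 0.36 with 5 of 33 genes risen (10 adjusted over the list alone, camera adjusted p = 0.0017), and cholesterol synthesis one of 0.33 with Scd2 risen (1.86 ± 0.27, camera adjusted p = 0.0044). With an estimated correlation each of the last 2 lists had an adjusted p = 0.94.

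At 48 h against time zero (4 arrays against 4), Cdkn2b rose by 6.04 ± 0.54 (adjusted p = 2.5e-06), Il17re by 5.38 ± 0.43, Ppef1 by 4.67 ± 0.60, with all 4 time zero arrays at the floor (2.71 with a floor of 0.2 of the median), Fgl2 by 4.37 ± 0.31 and the alarmin Il33 by 4.17 ± 0.63. Aldh3a1, an aldehyde dehydrogenase, rose by 4.06 ± 0.28, Entpd1 by 3.95 ± 0.48, Mustn1 by 3.83 ± 0.37, Lgals9 by 3.69 ± 0.31 and Gnat2 by 3.69 ± 0.81. Igfbp5 fell by 6.42 ± 0.71 (adjusted p = 2.2e-05). Dhrs7c (-4.58 ± 0.40), Id2 (-3.96 ± 0.44), the water channel Aqp5 (-3.54 ± 0.74), Tenm4 (-3.41 ± 0.58) and Cd74 (-3.37 ± 0.54, with both conditioned arrays at the floor) fell. So did Tbc1d10c (-3.28 ± 0.74), Perm1 (-3.0 ± 0.30), Cpne6 (-2.79 ± 0.67) and Pdia2 (-2.73 ± 0.26). The largest adjusted p among these 20 genes was 0.018, for Cpne6. The call of Tbc1d10c ended without the 3 arrays that stood apart, that of Gnat2 with no filter on level (adjusted p = 0.061) and that of Aqp5 with a floor of 0.2 of the median (-1.76, adjusted p = 0.073). That floor also gave smaller changes for Cdkn2b (4.86), Il17re (4.21), Il33 (3.68), Gnat2 (2.38), Igfbp5 (-5.41), Dhrs7c (-3.95), Cd74 (-2.36), Tbc1d10c (-2.03) and Cpne6 (-1.86), each with arrays at the floor.

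Of 23694 probes 1639 changed, 1270 higher and 369 lower. With quantile normalization 3758 changed, 2105 higher and 1653 lower, and without the 3 arrays 3509 changed, 1820 higher and 1689 lower. On the smaller design 401 of 407 called genes had the same sign.

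Most mitosis genes rose in both media by 48 h. Of 42 measured genes 34 rose and none fell (37 adjusted over the list alone), with a median of 1.45 (camera adjusted p = 1.3e-24, adjusted p = 0.26 with an estimated correlation). The spindle checkpoint gene Mad2l1 rose by 1.80 ± 0.26, Kif20a by 1.87 ± 0.27, Kif23 by 1.85 ± 0.27 and securin, Pttg1, by 1.89 ± 0.28. Ccnb1 rose from 597 ± 184 at time zero to 2264 ± 727 in unconditioned and 1503 ± 69.9 in conditioned medium, and Mki67 from 500 ± 159 to 1280.2 ± 101 and 1432 ± 109. Their changes were 1.59 ± 0.28 (adjusted p = 9.7e-04) and 1.43 ± 0.27 (adjusted p = 0.0017), with Cdk1 at 1.77 ± 0.34 (0.0022) and Ccnd1 at 1.27 ± 0.29 (0.0073). In each medium against time zero, 29 of the 42 genes rose, with list medians of 1.62 in unconditioned and 1.22 in conditioned medium. All 18 mitosis genes on the smaller design were above the median of all genes there. Of 33 DNA replication genes 8 rose (11 adjusted over the list alone, median 0.44, camera adjusted p = 3.8e-04, adjusted p = 0.94 with an estimated correlation), among them Uhrf1 (1.90 ± 0.27) and the ribonucleotide reductase subunit Rrm2 (2.18 ± 0.36).

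**Figure D3:**
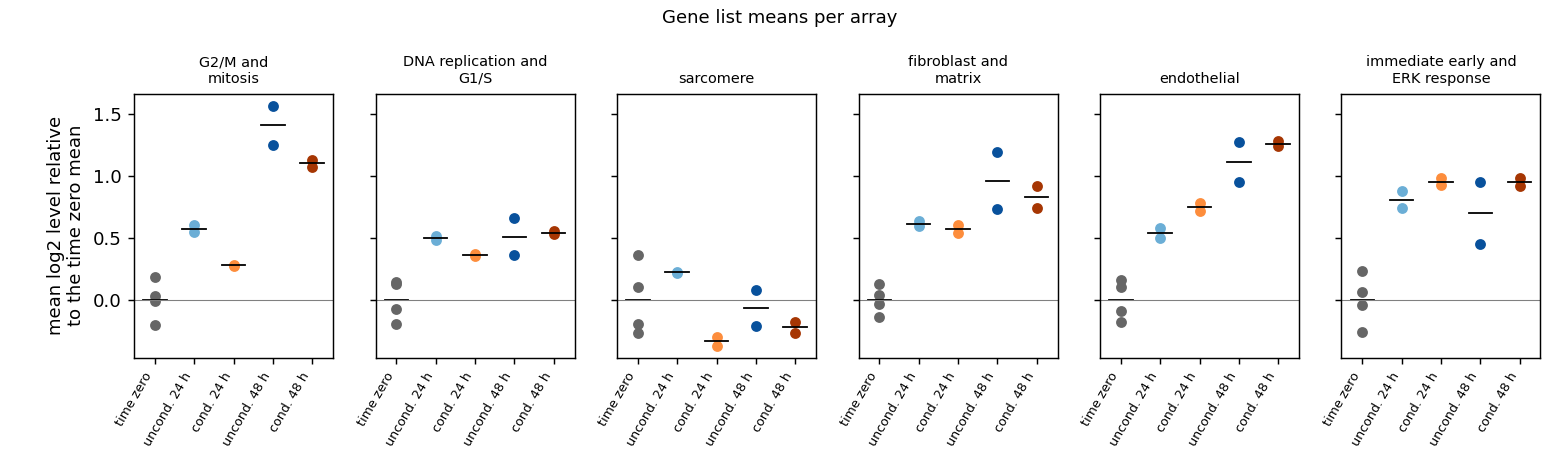
Mean log2 level of each gene list on each array of the larger design, relative to the mean of the 4 time zero arrays, for 6 lists. Points are arrays and bars are group means. The mean of the mitosis list was 1.41 in unconditioned and 1.10 in conditioned medium at 48 h.

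Markers of other cell types moved apart. Of 18 endothelial genes 13 rose and 1 fell, over all probes and adjusted over the list alone (median 1.49, camera adjusted p = 3.2e-08, adjusted p = 0.27 with an estimated correlation), with Tek at 2.79 ± 0.28, Esam at 1.99 ± 0.26, Vwf at 2.40 ± 0.34 and Nos3 at 1.84 ± 0.28. Of 25 fibroblast and matrix genes 12 rose and none fell (14 adjusted over the list alone, median 1.03, camera adjusted p = 3.9e-08, adjusted p = 0.55 with an estimated correlation), with Lox at 2.47 ± 0.26, Fbln2 at 2.47 ± 0.27 and the collagen Col1a1 at 1.14 ± 0.27. Of 12 smooth muscle and pericyte genes 4 rose (5 adjusted over the list alone, median 0.56, camera adjusted p = 0.0025, adjusted p = 0.89 with an estimated correlation), led by Cspg4 (2.30 ± 0.34). Leukocyte genes had a median of -0.55 (camera adjusted p = 0.0080, adjusted p = 0.26 with an estimated correlation), with Cd14 risen by 1.02 ± 0.25, Cd74 fallen, and the other 11 not past the test. That list no longer passed with quantile normalization (-0.48, camera adjusted p = 0.11) or without the 3 arrays that stood apart (-0.38, 0.15).

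Of 25 immediate early and ERK response genes 12 rose (15 adjusted over the list alone, median 0.83, camera adjusted p = 5.6e-06, adjusted p = 0.89 with an estimated correlation). Of 27 cholesterol synthesis genes 4 rose (9 adjusted over the list alone, median 0.50, camera adjusted p = 0.0015, adjusted p = 0.94 with an estimated correlation), led by the desaturase Scd2 (2.52 ± 0.27). The respiratory chain had a median of -0.13 with none of 36 genes past the test (camera adjusted p = 0.039, adjusted p = 0.97 with an estimated correlation), and it no longer passed without the filter on level (-0.08, 0.071). Sarcomere genes had a median of -0.08 (camera adjusted p = 0.082), and Tpm1 rose by 1.39 ± 0.27 while Myom2, Tcap and Myl7 fell (-1.91 ± 0.29, -1.58 ± 0.29 and -1.18 ± 0.25). On the smaller design Tpm1 was at -0.34.

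**Figure D4:**
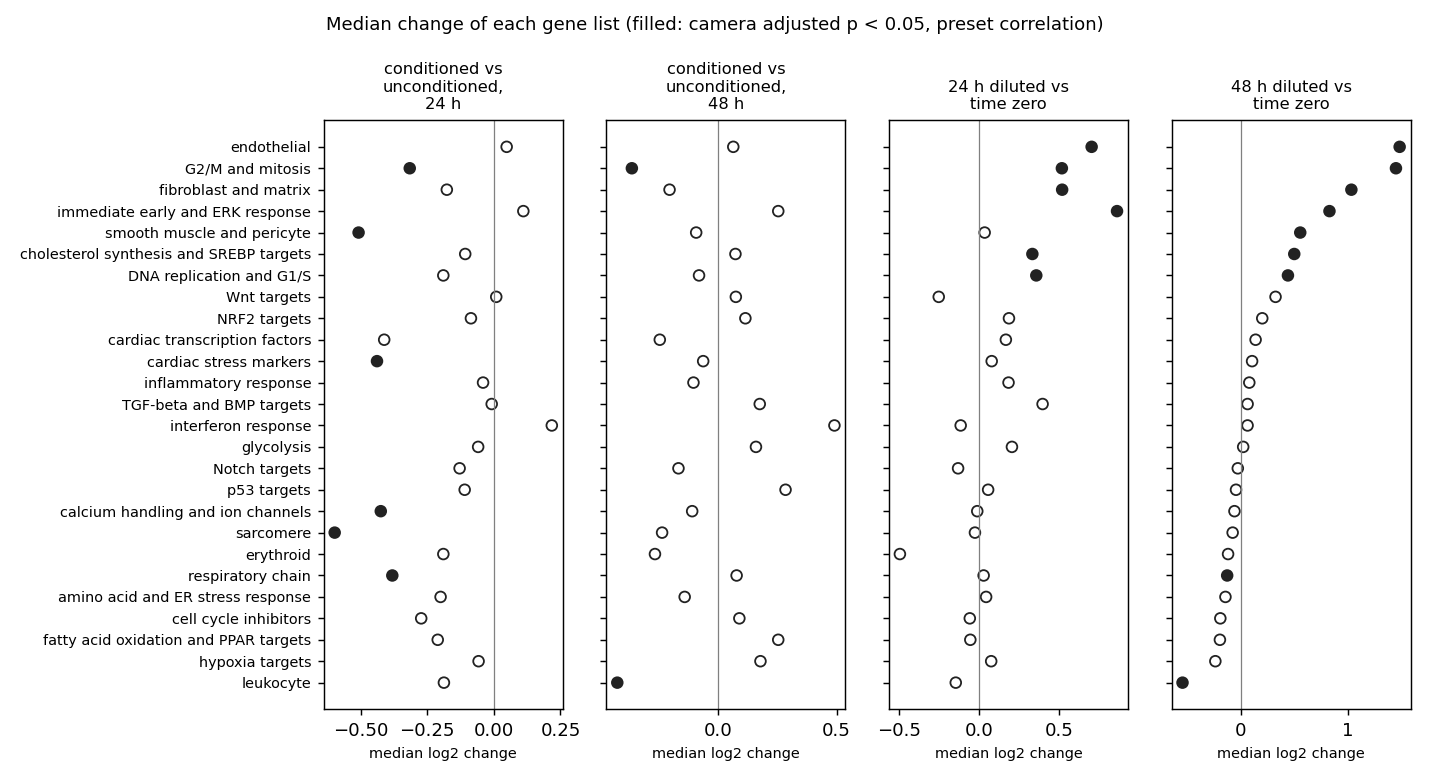
Median log2 change of each of 26 gene lists in 4 comparisons, on horizontal axes that differ between panels. Filled points passed camera with a preset correlation and open points did not. At 48 h against time zero endothelial and mitosis genes lay highest, at 1.49 and 1.45, and leukocyte genes lowest, at -0.55.

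Between 24 h and 48 h (4 arrays of both media against 4), 5 probes changed, and 102 with quantile normalization, 70 higher and 32 lower. Of the 5, 4 had a gene name and 1 had none. Myh3 rose by 2.23 ± 0.32 and Serpinb1a by 2.01 ± 0.29, while Dhrs7c (-2.70 ± 0.40) and Pdia2 (-1.60 ± 0.26) fell, each with an adjusted p = 0.024. All 5 calls ended with no filter on level, with Pdia2 at an adjusted p = 0.26, and the call of Pdia2 also ended with a pseudocount (-1.24, adjusted p = 0.093). Myh3, Serpinb1a and Dhrs7c were named after their values were seen. Values that did not pass here, but did with quantile normalization (adjusted p from 0.0012 to 0.021) and some other settings, included Parpbp, a gene of DNA repair (1.56 ± 0.27, adjusted p = 0.12), the kinetochore gene Ska1 (1.45 ± 0.26, 0.16), calponin, Cnn1 (1.38 ± 0.24, 0.14), and Derl3 (-1.31 ± 0.26, 0.12).

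Of 42 mitosis genes 41 were above the median of all probes, with a median of 0.93 (camera adjusted p = 8.7e-45, adjusted p = 0.12 with an estimated correlation). None passed over all probes and 30 rose when adjusted over the list alone. The list had an adjusted p = 0.014 with an estimated correlation and quantile normalization. Endothelial genes had a median of 0.66 (camera adjusted p = 1.7e-08, adjusted p = 0.38 with an estimated correlation), fibroblast and matrix genes one of 0.36 (2.1e-05, adjusted p = 0.65 with an estimated correlation) and smooth muscle genes one of 0.22 (1.3e-04, adjusted p = 0.65 with an estimated correlation). The amino acid and ER stress response had a median of -0.22 (camera adjusted p = 0.044) and the respiratory chain one of -0.13 (0.0068), both with an adjusted p = 0.93 with an estimated correlation, and the respiratory chain no longer passed with quantile normalization (-0.01, 0.55).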

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

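The tests in this part were planned, and only the joined settings named as such were chosen after the result was seen. In 5 of 66 sets of 4 time zero values, 1 array lay far from the other 3, measured as its gap to the nearest of them over the whole range, against the 95% critical value of Dixon for 4 values. Chance gives about 1 in 20. The ratio was 0.868 for Mustn1 (replicate 4, log2 intensity 4.12 against 5.76 to 6.01), 0.903 for Abi3 (replicate 6, 3.97 against 6.07 to 6.29) and 0.964 for Plcl1 (replicate 5, 6.75 against 7.49 to 7.52). It was 0.862 for Ddx25 (replicate 4, 8.73 against 7.24 for the nearest) and 0.875 for the mean of 4 erythroid genes (replicate 5, -0.19 against -2.16 to -1.91). The 5 results lay in 3 different arrays, and no explanation was tested.

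The effect of conditioned medium differed between 24 h and 48 h for 6 gene lists by camera on the difference itself. The median difference was 0.31 for the sarcomere (adjusted p = 0.0042), 0.23 for cardiac stress markers (0.010), 0.45 for the respiratory chain (9.8e-05), 0.43 for fatty acid oxidation and PPAR targets (0.0023), 0.37 for glycolysis (0.040) and 0.41 for smooth muscle and pericyte genes (0.0035). With an estimated correlation each had an adjusted p = 0.92, and with quantile normalization 2 lists passed. An estimated correlation joined with quantile normalization, chosen after the result was seen, gave 0 lists. In each of the 6 lists unconditioned 48 h replicate 2, an array that stood apart, lay below replicate 3, which adds to the differences. For the respiratory chain the list means relative to time zero were -0.30 and -0.18, and for the sarcomere -0.21 and 0.08. No biological explanation was tested.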

How the results depend on the processing

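Scaling to the 75th percentile, leaving out the 3 arrays that stood apart, and an estimated correlation joined with another setting were chosen only after the results were seen. Results are given in the order conditioned against unconditioned medium over both times, at 24 h and at 48 h, the difference of these effects, 24 h against time zero, 48 h against time zero, and 48 h against 24 h. The numbers of calls were 218, 58, 35, 0, 743, 1639 and 5. With quantile normalization they were 920, 302, 170, 0, 1821, 3758 and 102, and with cyclic loess 1639, 573, 341, then 2307, 4554 and 244 for the last 3 results. Scaling to the 75th percentile gave 895 (530 higher, 365 lower), 262, 153, 0, 1619 (1168, 451), 3605 (2067, 1538) and 118. Without the 3 arrays the counts were 1818 (991, 827), 814, 294, 17, 1713, 3509 and 299. Of the 218 calls 215 were shared with quantile normalization, 217 with the 75th percentile and 218 without the 3 arrays. Of the 1639 calls at 48 h against time zero 1623, 1618 and 1558 were shared.

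Counts over 1.5 times away under other settings were, with no filter on level, 83, 12 and 10 for the medium, 406 for 24 h against time zero and 0 for 48 h against 24 h. With no intensity trend they were 129, 29 and 22 for the medium, 494 for 24 h against time zero and 1 for 48 h against 24 h. Array weights gave 1075, 828 and 79 for the medium, 1388 for 24 h against time zero and 74 for 48 h against 24 h. Only the groups compared gave 935, 622 and 96 for the medium, 1006 for 48 h against time zero and 66 for 48 h against 24 h. Both tables fitted together, with 4613 genes, gave 409 and 749 against time zero and 30 for 48 h against 24 h. These are counts of genes, not on the scale of the main counts of probes. The main fit called 220, 407 and 2 of the same 4613 genes in these comparisons. The smaller table alone, with 6934 probes, gave 601, 121, 221, 110, 170, 556 and 129. For 48 h against 24 h a filter at the 50th percentile gave 8 and a pseudocount 2. The smaller table has 1 array in each medium group, assumed to vary like the others. The cause was not tested for any setting.

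Of 26 gene lists 4, 6, 2, 6, 6, 9 and 6 passed. An estimated correlation gave 0 for every comparison. Joined with quantile normalization it gave 1, 2, 1, 0, 1, 0 and 2, joined with leaving out the 3 arrays 0, 0, 0, 0, 0, 0 and 2, and joined with the fit of both tables it gave 0, 0, 0, 0, 0, 0 and 1. In place of camera, fry gave 2, 0, 1, 0 and 0 for the first 5 comparisons and 0 for the last. For the medium over both times quantile normalization gave 9, no filter 7, the 75th percentile 7 and leaving out the 3 arrays 10. At 48 h quantile normalization gave 5, no intensity trend 4, the fit of both tables gave 1, and leaving out the 3 arrays 5, and for the difference of the effects quantile normalization gave 2. The cause was not tested.

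Leaving out each array in turn, the counts of calls ran from 93 to 560, 19 to 129, 11 to 133, 0 to 15, 342 to 1309, 846 to 2026 and 0 to 20, where a lone array was assumed to vary like the other groups. Over both times the medium count was 102 and 100 without conditioned 24 h replicate 2 or 3, 112 and 93 without conditioned 48 h replicate 2 or 3, 118 without unconditioned 24 h replicate 3 and 560 without time zero replicate 4. At 24 h it was 19 and 26 without conditioned 24 h replicate 2 or 3, 34 without unconditioned 24 h replicate 3 and 129 without time zero replicate 4. At 48 h it was 21 and 19 without conditioned 24 h replicate 2 or 3, 22 without unconditioned 24 h replicate 3, 97 without unconditioned 48 h replicate 3, 11 without conditioned 48 h replicate 3 and 133 without time zero replicate 4. The difference of the effects went from 0 to 4 and 11 without conditioned 24 h replicate 2 or 3, 15 and 4 without unconditioned 24 h replicate 2 or 3, 12 and 5 without unconditioned 48 h replicate 2 or 3, and 10 and 4 without conditioned 48 h replicate 2 or 3. For 24 h against time zero it was 371 and 342 without conditioned 24 h replicate 2 or 3, 460 and 399 without unconditioned 24 h replicate 2 or 3, and 473 and 1309 without time zero replicate 5 or 6. For 48 h against time zero it was 900 and 846 without conditioned 48 h replicate 2 or 3. For 48 h against 24 h it was 0, 18 and 1 without time zero replicate 3, 4 or 5, 20 and 8 without unconditioned 48 h replicate 2 or 3, 10 and 2 without conditioned 48 h replicate 2 or 3, 12 without conditioned 24 h replicate 3 and 19 without unconditioned 24 h replicate 2. Numbers of lists ran from 3 to 7, 6 to 7, 2 to 4, 2 to 7, 6 to 7, 8 to 10 and 4 to 9. They were 7 for the medium over both times without conditioned 24 h replicate 2, unconditioned 48 h replicate 2 or time zero replicate 5, and 4 at 48 h without replicate 2 of either 48 h group. The difference of the effects had 2 without unconditioned 48 h replicate 2 or conditioned 24 h replicate 3.

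On the smaller design the share with the same sign was 95.9% for the medium over both times, 99.5% for 24 h and 98.5% for 48 h against time zero. It was 100% for the medium with no filter (24 of 24 genes) or with genes above the 50th percentile in both tables (29 of 29), and 100% for 24 h against time zero with the latter (141 of 141). For 48 h against time zero it was 96.1% with quantile normalization (1048 of 1091) and 90.9% with no filter (310 of 341). Among 1226 values of named genes under other settings 1109 kept direction and side of the threshold, 62 no longer passed, 55 newly passed and 0 reversed. Among 468 values of lists that passed, 266 stayed past the threshold and 202 did not, with 0 reversed. Leaving out arrays, 1114 of 1200 gene values and 439 of 468 list values stayed. No paired analysis was possible because the labels carry no replicate numbers that link dishes across groups. Signal near background limits dim probes, and the size of a change against arrays at the floor depends on the floor.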

Other observations

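The tests chosen only after the result was seen were those on cell type markers, on the arrays that stood apart, on the agreement of splits with the smaller design and on 48 h against 24 h with the medium in the model, and the comparison of time and medium effects that follows. That comparison shared no arrays. Of 118 genes called lower at 48 h than at time zero, 93 (78.8%) were lower in conditioned than in unconditioned medium at 24 h, with a median effect of -0.57. Of 711 genes called higher 290 (40.8%) were lower, with a median of 0.15, against 49.0% of all 9953 genes. Spearman's correlation was 0.19.

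Other splits of the same 8 arrays into 4 and 4 were counted in simpler models, so that the real counts differ from those above. For conditioned against unconditioned medium time was kept in the model, which leaves out the split by time. There 1 of 34 splits, the real one, gave as many calls (243, highest other 1). That argues against a chance split of these arrays, although 1 of 34 is the smallest share such a test can give. The other 3 comparisons pooled the media. For 24 h against time zero 1 of 35 splits gave as many (703, highest other 1), which argues against a chance split with the same limit. Against time zero at 48 h, 2 of 35 splits gave as many (1467), and these counts did not exclude chance. The highest other, 1985, set time zero replicates 3, 4 and 5 and unconditioned 48 h replicate 2 apart, which include the 3 arrays that stood apart, and without those 3 arrays 1558 of the 1639 calls were shared. Between 24 h and 48 h all 35 splits gave as many as the real 0, and the highest other, 220, split by medium. With the medium kept in the model 1 of 34 splits gave as many calls (4, highest other 2), but with so few calls, in a test chosen after the first, chance stays open for this count.

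Agreement with the arrays of the smaller design was counted over all 35 splits of each comparison, as the absolute Spearman correlation of the change over 4613 shared genes. The real split was the only 1 of 35 as high for 48 h against time zero (0.72, highest other 0.66). There 401 of 407 called genes had the same sign, against 78.0% of all shared genes. This measure was chosen after the counts of calls had not excluded chance. Since 1 of 35 is the smallest share it can give, it argues against chance without excluding it. The real split was also the only 1 of 35 as high for 24 h against time zero (0.62, highest other 0.61) and for 48 h against 24 h (0.49, highest other 0.44). The margin was small for 24 h against time zero, while for 48 h against 24 h it was close to that for 48 h against time zero. The same limit on the smallest share holds for both, and chance was not excluded. For conditioned against unconditioned medium 5 of 35 splits were as high (0.42, highest other 0.53), so over all genes this measure did not exclude chance there, while 47 of 49 called genes had the same sign, against 64.1% of all shared genes.

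Mitosis genes were higher at 48 h than at time zero (median 1.45). A lower share of cardiomyocytes alone would raise markers of all other cell types alike. Among genes above the median level leukocyte markers (8 of 13 genes) lay below fibroblast markers (22 of 25) by -1.39 (permutation of genes, p = 0.0032). These markers did not rise alike, but the test held no mitosis genes and shuffled genes rather than arrays. It cannot decide whether a lower share raised the mitosis genes, which stays open. Without the 3 arrays that stood apart the median was 1.36 (camera adjusted p = 7.7e-23, adjusted p = 0.064 with an estimated correlation, against 0.26 with them), so its size argues against those arrays as the cause, although the list did not pass with an estimated correlation either way. Growth of a non-muscle cell type stays open, since fibroblast and endothelial markers rose as well, and added time, dilution and handling could not be separated. Whether cardiomyocytes themselves divided was not tested.

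Over both times sarcomere genes lay lower in conditioned than in unconditioned medium (median -0.33). The gap was larger at 24 h than at 48 h under median scaling, a difference that did not pass with quantile normalization. A lower share of cardiomyocytes in conditioned dishes would raise markers of other cells. Fibroblast, smooth muscle and endothelial markers had a median of -0.17 (95% interval over resampled genes -0.24 to -0.03, 55 genes) relative to all probes. Without that centring it was -0.085 (-0.15 to 0.06), so a lower share stays open. The intervals here hold the spread between genes, not between arrays. After the first value was seen, smooth muscle genes were left out, because neonatal cardiomyocytes may express some of them, and the median of the other 43 genes was -0.12 (-0.23 to 0.02), which decides nothing either. Without the 3 arrays that stood apart the sarcomere median was -0.37. Time zero arrays do not enter this comparison, and unconditioned 48 h replicate 2 had a lower sarcomere mean than replicate 3 (-0.21 against 0.08). Leaving it out was therefore bound to widen the gap in list means, so this test could not have pointed to those arrays. With all arrays the list had a camera adjusted p = 0.95 with an estimated correlation. A change within cardiomyocytes stays open as a hypothesis, which was not tested here, and sarcomere transcripts measured in single cardiomyocytes from both media would decide it.

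Reg3b and Osmr were among the genes most raised by conditioned medium, which led to the hypothesis that signalling through gp130 and STAT3 may be raised, tested on a list of targets drawn up after Reg3b, Osmr and 3 other genes had been seen, leaving those out, when 10 of its members had already been tested in the fixed lists, Cebpd and Icam1 among them. Its 20 measured genes had a median change of 0.41 (95% interval over resampled genes 0.05 to 0.82), and 17 were above the median of all probes. Camera gave p = 2.5e-04, but p = 0.11 with an estimated correlation. Intervals of this kind hold the spread between genes, not between arrays. At 24 h the median was 0.18 with an interval that crossed 0 (-0.05 to 0.91), 11 of 20 were above and none was called, and at 48 h it was 0.62 (0.10 to 0.96), with 17 above and none called. Over both times Cebpd and Icam1 were called, and 6 genes when adjusted over the list alone, while Socs3 stood at 0.04 ± 0.40, Serpina3n at -0.62 ± 0.35 and Hp at -0.64 ± 0.36. On the smaller design the median of 14 genes was 0.14 with Icam1 at -0.01, so the signal is consistent with the hypothesis without singling it out, and phosphorylated STAT3 measured in both media would decide it.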
